A study of Mus musculus with 23 samples.

How the data were processed

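Poly(A)-selected RNA from mouse hippocampus was sequenced in 23 libraries of 7 groups. The groups and replicate numbers were taken from the sample titles. Per the labels' protocols, hippocampi were dissected, frozen in Trizol, and the selected RNA was size-selected before sequencing. Per the submitters' processing notes, the reads were handled with FastQC 0.11.7, Trimmomatic 0.36.5, HISAT2 2.1.0 and featureCounts 1.6.0.6 on genome build GRCm38, and DESeq2 2.11.40.2 is also listed. The annotation release, the strand setting and the treatment of reads that align to several places are not given in the sources used here. The files the authors deposited hold whole-number counts per gene, 1 file per library, with no normalization. Per the file headers, the column name of the Lsd1het files names a raw read file where those of the other groups name an alignment. A rule for multiple alignments that is not known leaves the values of pseudogenes, near-identical copies and overlapping or antisense genes uncertain, and reads of a transgene or virus are not told from those of the mouse gene.

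Each file listed the same 54232 gene identifiers, of which 40290 had reads in at least 1 library. Symbols and coordinates came from a GENCODE annotation of GRCm38, which matched 54165 identifiers. The 67 others held 0.0184% of the reads and were kept under their identifiers. Totals ran from 15451494 to 24644977 counted reads per library. Within groups, no pair of libraries agreed within sampling noise: the smallest chi-square per gene was 11.6, between PS19_HA replicates 1 and 2.

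Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, robust estimation and the filter filterByExpr by group (minimum count 10, minimum total 15). Calls were genes with a Benjamini-Hochberg adjusted p under 0.05. The 14 libraries of the 9-month cohort shared 1 fit (20122 genes), the 9 of the 11-month cohort another (19290 genes), and the difference between the cohorts' tau effects was fitted over all 23 (20931 genes). CPM and log2 CPM (prior count 2) were computed from the deposited counts, and errors of CPM are SDs over libraries. DESeq2 1.42.0 was the second tool. Its adjusted p was undefined for 188 genes of the 9-month comparisons, for 17, 17 and 1139 genes of the 11-month comparisons in the order given in the results, and for 113 genes of the difference between cohorts. Those genes stayed out of its calls.

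Named genes followed a rule fixed with the comparisons, the gene lists and the first set of alternatives before the data were examined. For each comparison it took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM and groups that did not overlap. Where fewer than 5 genes were called, the 5 with the lowest p were named as values. Up to 4 called members of each list were named, and Kdm1a, Mapt and Prnp in every group. Predicted genes, pseudogenes and sex markers were counted, not named; exceptions were chosen after their values were seen. Since edgeR called few genes, the same rule was also applied to DESeq2's calls, a choice made after the calls were seen. Of the genes so taken, 1 is not reported here.

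There were 31 fixed gene lists: homeostatic microglia, disease-associated microglia, complement and Fc receptors, interferon response, antigen presentation, T cells, reactive astrocytes, astrocyte core, oligodendrocytes and myelin, oligodendrocyte precursors, synapse, CA1 pyramidal neurons, CA3 pyramidal neurons, dentate granule neurons, GABAergic neurons, neurogenesis, immediate early genes, oxidative phosphorylation, pluripotency and stem cell factors, LSD1-CoREST complex, p53 targets, unfolded protein and integrated stress response, cholesterol synthesis, heat shock, endothelium, mural cells and fibroblasts, choroid plexus, red blood cells, thalamus, striatum and neocortex. No list shares more than 1 gene with another. Lists were tested on log2 CPM with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, whose test asks whether the genes of a list move, on balance, 1 way. Mean list levels per library were also compared by exact two-sided permutation tests, whose smallest p is 0.0286 for 4 libraries against 4 and 0.1 for 3 against 3.

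The same replicate numbers recur across groups. They were taken to pair libraries where every pair of same-numbered libraries had deviations from the group means that correlated above 0.1 across genes. The correlations were 0.5 to 0.82 over the 4 pairs of PS19 and WT, 0.31 to 0.54 for PS19_Lsd1het and WT, 0.3 to 0.48 for PS19_Lsd1het and PS19, 0.11 to 0.3 over the 3 pairs of PS19_HA and WT_HA, and 0.12 to 0.47 for PS19_LSD1 and WT_HA. Of the libraries of the first-named group, 4 of 4, 2 of 4, 0 of 4, 3 of 3 and 2 of 3 in the same order correlated best with their own number. The pairing thus comes from the data, since no label says what the numbers share.

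Alternatives were DESeq2, its size factors within edgeR, no filter on low counts, a minimum log2 change of 1, the replicate number as a block, a sex covariate at 11 months, the compared groups alone, all 23 libraries together, and each library left out in turn. Added after the data were seen were a covariate for replicates 1 and 2 against 3 and 4, fits of either set alone, fits without libraries over 10% mitochondrial counts, robust estimation off, and DESeq2 with the block, with the 2-level covariate and without single libraries. Simulated counts with 200 genes changed by known folds were run through the same fits. They were drawn independently for each gene and library, without replicate sets, pairing or correlation between genes. The shares found and the p-values of planted lists thus do not give the power for the real genes and lists. At 9 months edgeR found 19.4% of 2-fold, 73.1% of 4-fold and 90.9% of 8-fold changes among 19791 genes with 2 false calls, and DESeq2 found 31.3%, 86.6% and 97% with 31. In the comparison of PS19_HA with WT_HA, edgeR found 41.8%, 92.5% and 95.5% among 18988 genes with 11 false calls, and DESeq2 59.7%, 97% and 97% with 54. A list of 25 changed genes planted at 9 months gave p = 4.57e-22 by camera, 2.65e-06 with an estimated correlation and 6.76e-07 by fry, and at 11 months 1.32e-44, 6.67e-06 and 3.54e-07. An unchanged list gave 0.148, 0.225 and 0.195 at 9 months and 0.395, 0.519 and 0.294 at 11 months.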

Results

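Hippocampal poly(A) RNA of C57BL/6 mice was profiled in 2 cohorts. The first, at 9 months of age, held 4 wild-type libraries (WT), 4 of mice with a mutant tau transgene (PS19, a widely used model of tauopathy), 4 of PS19 mice heterozygous for Lsd1 (PS19_Lsd1het) and 2 of Lsd1 heterozygotes without the transgene (Lsd1het). The second, at 11 months, had received an adeno-associated virus with neuron-specific expression in the hippocampus: 3 libraries were of wild-type mice with the HA control virus (WT_HA), 3 of PS19 mice with that virus (PS19_HA) and 3 of PS19 mice with a virus expressing LSD1 (PS19_LSD1). LSD1, the product of Kdm1a, is a histone lysine demethylase. Counted reads per library ranged from 15743147 to 24110989 in WT, 16214938 to 21797808 in PS19, 15451494 to 24617197 in PS19_Lsd1het, 18799229 to 22603468 in Lsd1het, 19646984 to 24551633 in WT_HA, 21715577 to 23644702 in PS19_HA and 16579034 to 24644977 in PS19_LSD1. The labels do not state that the libraries come from separate animals, so p-values measure only the spread between these samples, which may be technical. Mitochondrial genes took 33.9% of the counts in WT replicate 3, 16.1% in PS19 replicate 3 and 16.2% in WT_HA replicate 2, against 2.86% to 6.04% in the others. At 9 months, replicates 3 and 4 of every group that had them lay apart from replicates 1 and 2 on the first principal component, which held 51.7% of the variance, so values within either set are given beside the main lists. By Xist and Y-linked genes the 9-month libraries were all male-type, and each 11-month group mixed both types. Biological coefficients of variation were 0.423 at 9 months and 0.243 at 11 months.

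The labels were first checked with the genes they name. Kdm1a (chromosome 4, 136550540 to 136602723, GRCm38) stood at 55.1 ± 5.09 CPM in WT, 53 ± 5.68 in PS19 and 42.5 ± 10 in PS19_Lsd1het (SD, n = 4 each) and at 35.3 ± 0.701 in Lsd1het (SD, n = 2). The log2 difference of Lsd1het from WT was -0.64 (SE 0.23; adjusted p = 0.805 by edgeR and 0.802 by DESeq2) and that of PS19_Lsd1het from WT was -0.38 (SE 0.18; adjusted p = 0.798 by edgeR and 0.521 by DESeq2). With the replicate number as a block the latter reached adjusted p = 0.166 by edgeR and passed by DESeq2 at -0.42 (adjusted p = 0.026). The 4 PS19_Lsd1het libraries read 34.9, 34.6, 55.9 and 44.5 CPM, so the library labelled PS19_Lsd1het replicate 3 lay at the WT level, and directions drawn from that group include it. At 11 months Kdm1a stood at 65.3 ± 2.47 CPM in WT_HA, 63.2 ± 1.27 in PS19_HA and 5260 ± 4990 in PS19_LSD1 (SD, n = 3 each), whose libraries read 11000, 3010 and 1790. It was 83.2-fold above PS19_HA (log2 difference 6.38, SE 0.67), which passed by DESeq2 (adjusted p = 1.27e-18) but not by edgeR (adjusted p = 0.0895). Without PS19_LSD1 replicate 1 the log2 difference was 5.25 (edgeR adjusted p = 0.000175), and without replicate 3 it was 6.79 (0.00919). Against WT_HA it was 80.5-fold higher and passed by both tools (adjusted p = 0.0312 by edgeR and 3.02e-18 by DESeq2). For gene Kdm1a, PS19_LSD1 against WT_HA at 11 months, the log2 difference was 5.2 without PS19_LSD1 replicate 1. That edgeR call was lost with the block (0.0702), the sex covariate (0.0894), no filter (0.507) or the compared groups alone (0.182), without WT_HA replicate 1 (0.274), 2 (0.493) or 3 (0.256), and without PS19_LSD1 replicate 2 (0.0712). The log2 difference was 6.33 with all libraries and 6.02 to 6.61 in these fits.

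Mapt, the mouse tau gene (chromosome 11, 104231390 to 104332090), stood at 465 ± 68.3 CPM in WT, 587 ± 128 in PS19, 593 ± 78.8 in PS19_Lsd1het and 497 ± 42.8 in Lsd1het. At 11 months it stood at 491 ± 26.5 in WT_HA, 540 ± 13.9 in PS19_HA and 524 ± 23.6 in PS19_LSD1, with n as above. Prnp (chromosome 2, 131909928 to 131938429), whose promoter drives the PS19 transgene, stood at 766 ± 129 CPM in WT and 854 ± 68.6 in Lsd1het against 1620 ± 133 in PS19 and 1560 ± 353 in PS19_Lsd1het. At 11 months it read 684 ± 53.9 in WT_HA against 1570 ± 84.3 in PS19_HA and 1530 ± 269 in PS19_LSD1. Its log2 difference between PS19 and WT was 1.08 (SE 0.22) and that between PS19_HA and WT_HA 1.2 (SE 0.15). DESeq2 called both (adjusted p = 3.41e-05 and 2.62e-10) and edgeR neither (adjusted p = 0.126 and 0.0799), though the latter passed with the replicate block (adjusted p = 0.0239). Lamr1-ps1, a pseudogene just upstream of Prnp (chromosome 2, 131904086 to 131904959), had reads in each library labelled PS19, PS19_Lsd1het, PS19_HA or PS19_LSD1 and 0 reads in each WT, Lsd1het and WT_HA library. It stood at 3.34 ± 0.971 CPM in PS19, 2.95 ± 0.596 in PS19_Lsd1het, 2.78 ± 0.536 in PS19_HA and 2.09 ± 0.689 in PS19_LSD1. The pseudogene was named after its values were seen, and its level is uncertain because near-identical ribosomal protein copies exist elsewhere.

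The comparison of PS19 with WT at 9 months asked what the tau transgene changed in the uninjected hippocampus. All 25 measured genes of the interferon response were higher in PS19, with a median log2 difference of 2.66, and the list rose as a group (camera, adjusted p = 1.16e-61, adjusted p = 0.0138 with an estimated correlation). That last call was lost with the replicate block (adjusted p = 0.0844) or a covariate for replicates 1 and 2 against 3 and 4 (0.0734). Adjusted over the list alone, edgeR called 25 members, against 0 over all genes, where DESeq2 called 21. Cxcl10, an interferon-induced chemokine (chromosome 5, 92346638 to 92348889), stood at 7.29 ± 4.93 CPM in PS19 and 0.155 ± 0.158 in WT (SD, n = 4 each; log2 difference 5.34, SE 0.76). DESeq2 called it (adjusted p = 3.82e-10) where edgeR did not (adjusted p = 0.0615; 0.0343 with the replicate block). The antiviral genes Ifit1 (12.4 ± 7.8 against 1.23 ± 0.471 CPM, adjusted p = 5.04e-07 by DESeq2), Ifi44 (9.12 ± 6.78 against 0.61 ± 0.309, adjusted p = 2.11e-06) and Mx1 (log2 difference 4.8, SE 0.86, adjusted p = 3.99e-06) were also called by DESeq2. The list held within replicates 1 and 2 alone (adjusted p = 9.52e-27) and within 3 and 4 alone (adjusted p = 1e-49). All 17 genes of antigen presentation were higher, at a median of 1.98, and the list rose (camera, adjusted p = 4.46e-28, adjusted p = 0.0193 with an estimated correlation; 2.5e-12 and 1.44e-22 within either set). With an estimated correlation this call, too, was lost with the block (adjusted p = 0.0844) or the covariate (0.0755). Of these edgeR called 13 adjusted over the list alone and 0 over all genes, and DESeq2 called 9. Cd74, the invariant chain of MHC class II, stood at 76 ± 103 CPM against 2.38 ± 1.93 and H2-Aa, a class II chain, at 28.1 ± 43.2 against 0.83 ± 0.367, so their SDs exceeded their means in PS19 (DESeq2 adjusted p = 1.35e-05 and 2.25e-05).

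Microglial and astrocyte lists rose in PS19 as well. With an estimated correlation the calls of disease-associated microglia, complement and reactive astrocytes were lost when the block (adjusted p = 0.0844 each) or the 2-level covariate (0.0734 each) was added. Of 30 disease-associated microglial genes 29 were higher, at a median of 1.82 (camera, adjusted p = 1.02e-41, adjusted p = 0.0138 with an estimated correlation; 8.3e-20 and 1.35e-31 within replicates 1 and 2 and within 3 and 4). In this list edgeR called 22 adjusted over the list alone and 0 over all genes, and DESeq2 called 14. Itgax, an integrin of activated microglia (chromosome 7, 128129547 to 128150657), stood at 19.5 ± 25.1 CPM in PS19 and 0.14 ± 0.0738 in WT, a log2 difference of 7 (SE 1.06) called by DESeq2 (adjusted p = 2.56e-11) and, with the replicate block, by edgeR (adjusted p = 0.0343; 0.0615 without it). Cst7, a cysteine protease inhibitor, stood at 8.9 ± 8.29 against 0.0864 ± 0.079, Clec7a, a pattern recognition receptor, at 17.8 ± 18.9 against 0.33 ± 0.151 and Gpnmb at 23.1 ± 11.9 against 4.02 ± 1.12 (DESeq2 adjusted p = 1.14e-09, 3.19e-08 and 1.12e-06). All 16 genes of complement and Fc receptors were higher, at a median of 1.91 (camera, adjusted p = 8.25e-31, adjusted p = 0.0138 with an estimated correlation; 8.84e-14 and 2.82e-24 within either set), with 13 called by edgeR adjusted over the list alone, 0 over all genes and 10 by DESeq2. The complement components C3 and C4b stood at 27.8 ± 22.1 and 304 ± 258 CPM against 2.02 ± 1.73 and 38.9 ± 20 (DESeq2 adjusted p = 3.34e-05 and 0.000751). All 24 genes of reactive astrocytes were higher, at a median of 1.81 (camera, adjusted p = 5.88e-37, adjusted p = 0.0138 with an estimated correlation; 1.47e-16 and 4.83e-28 within either set), with 18 called by edgeR adjusted over the list alone, 0 over all genes and 10 by DESeq2. The intermediate filament genes Gfap (chromosome 11, 102887336 to 102900912) and Vim stood at 1860 ± 1340 and 145 ± 107 CPM against 311 ± 71.8 and 28.4 ± 5.34 (DESeq2 adjusted p = 2.25e-05 and 0.000228), and Tgm1, a transglutaminase, at a log2 difference of 3.93 (SE 0.7, adjusted p = 7.31e-06). Mean levels of these lists separated PS19 from WT completely, as did those of the same lists in PS19_Lsd1het, with the smallest p an exact permutation test of 4 against 4 can give (p = 0.0286; adjusted p = 0.111 and 0.0985). Outside the lists, DESeq2 also called the chemokine gene Cxcl13 at 6.53 (SE 1.32) and Cd22, a sialic acid-binding receptor, at 4.77.

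Oligodendrocyte and myelin genes were higher in 17 of 17 at a smaller median of 0.46 and rose as a list (camera, adjusted p = 9.79e-08, adjusted p = 0.0268 with an estimated correlation, which became 0.126 with the block and 0.0825 with the 2-level covariate). Lists that rose by camera but not with an estimated correlation included homeostatic microglia (median 0.62, adjusted p = 5.49e-07, adjusted p = 0.127 with an estimated correlation), astrocyte core (0.29, adjusted p = 0.000362; 0.127) and p53 targets (0.4, adjusted p = 1.51e-05; 0.0599). Cholesterol synthesis (median -0.25, adjusted p = 3.96e-05, 0.268 with an estimated correlation) and striatal markers (-1.39, adjusted p = 2.62e-08; 0.0531) fell by camera, the latter not within replicates 1 and 2 alone (adjusted p = 0.192). Synaptic genes were lower in 30 of 32, at a median of -0.18 (camera, adjusted p = 0.00379, adjusted p = 0.278 with an estimated correlation; 0.0671 without PS19 replicate 4). Choroid plexus (median 0.82, camera adjusted p = 0.000485, 0.463 with an estimated correlation) was not called without WT replicate 1 (adjusted p = 0.229) or PS19 replicate 3 (0.225). GABAergic neurons (-0.21, adjusted p = 0.01, 0.0531 with an estimated correlation) were not called without WT replicate 3 (0.256) or PS19 replicate 3 (0.0864) or within replicates 1 and 2 (0.118). The unfolded protein and integrated stress response (0.27, adjusted p = 0.000445, 0.278 with an estimated correlation) was not called without WT replicate 3 (0.0929) or PS19 replicate 2 (0.182). Endothelium (0.22, adjusted p = 0.00385, 0.276 with an estimated correlation) was lost without WT replicate 1 (0.077), WT replicate 3 (0.0929) or PS19 replicate 1 (0.173), and within replicates 3 and 4 (0.201). Mural cells and fibroblasts (0.37, adjusted p = 0.0289, 0.408 with an estimated correlation) were lost without WT replicate 1 (0.111), 3 (0.151) or 4 (0.0704) or PS19 replicate 1 (0.9) or 3 (0.0945), and within replicates 3 and 4 (0.201). Oxidative phosphorylation (-0.07, adjusted p = 0.0231, 0.365 with an estimated correlation) was lost without WT replicate 1 (0.423) or 2 (0.114) or PS19 replicate 3 (0.396) or 4 (0.0653), and within replicates 3 and 4 (0.169). The other lists did not pass camera: T cells (adjusted p = 0.483), oligodendrocyte precursors (0.0814; 0.0369 with the replicate block), CA1 (0.436), CA3 (0.892) and dentate granule neurons (0.105), neurogenesis (0.436), immediate early genes (0.404), pluripotency and stem cell factors (0.703), the LSD1-CoREST complex (0.661), heat shock (0.367), red blood cells (0.27), thalamus (0.373) and neocortex (0.169). With the block and an estimated correlation, oligodendrocyte precursors did not pass. For neurogenesis and pluripotency factors the median (-0.02 and -0.03) and the direction of the test (up) differed in sign.

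Over all 20122 genes, edgeR called 1 gene between PS19 and WT, Lamr1-ps1 (adjusted p = 0.00171), which was at least 89.9-fold higher in PS19, taking 3 counts over the WT group as the floor. There were 787 genes at an unadjusted p under 0.05, against 1006 by chance. DESeq2 called 187 higher and 4 lower. Among the lower were mt-Co3, a mitochondrial gene with nuclear copies and so of uncertain level (3.11 ± 1.62 against 41.6 ± 53.8 CPM), and the calpain gene Capn11 (0.363 ± 0.232 against 2.03 ± 1.7; DESeq2 adjusted p = 0.0199). With the replicate block edgeR called 5 genes, among them Lamr1-ps1, Itgax and Cxcl10, and DESeq2 365. Among genes called, PS19 against WT at 9 months, edgeR gave 146 without PS19 replicate 2, 2 without PS19 replicate 3, and 0 when only the PS19 and WT libraries were fitted.

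**Figure D1:**
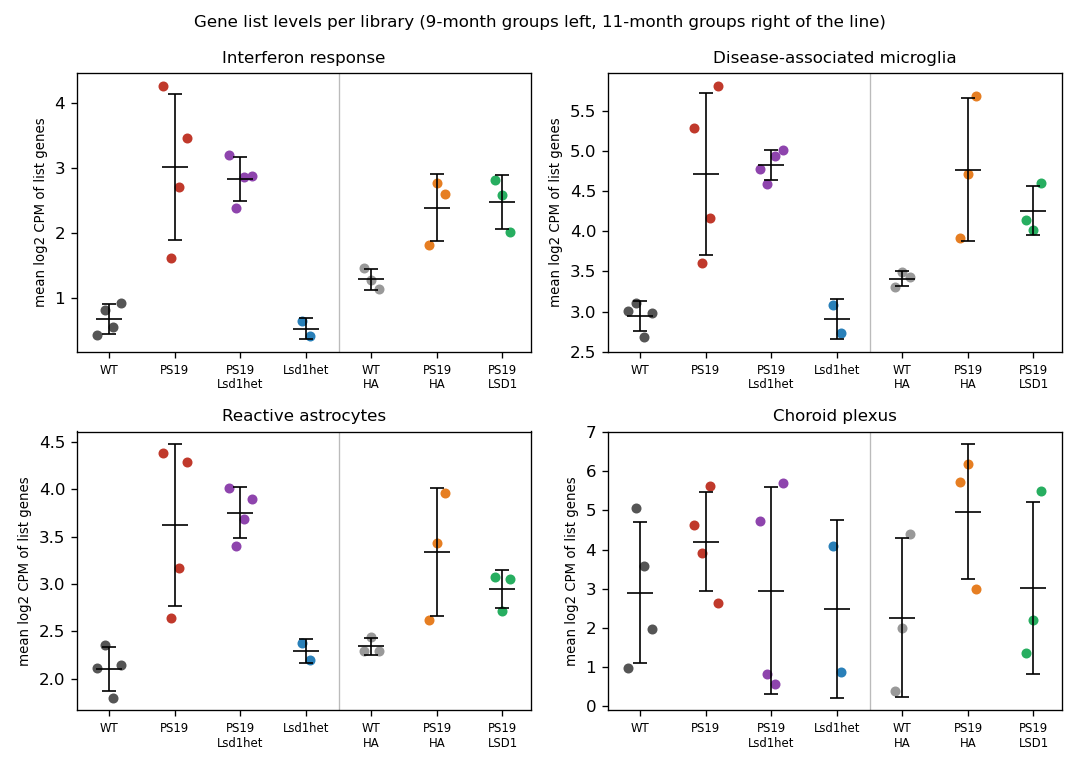
Mean log2 CPM of 4 gene lists (interferon response, disease-associated microglia, reactive astrocytes, choroid plexus) on the vertical axes, by group on the horizontal axes, with a point per library and bars for the mean ± SD; 9-month groups stand left of the line and 11-month groups right of it. Interferon response averaged 0.69 ± 0.23 in WT, 3.01 ± 1.12 in PS19 and 2.83 ± 0.33 in PS19_Lsd1het, while choroid plexus spread widely within groups, from 0.37 to 4.4 in WT_HA.

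PS19_Lsd1het libraries were compared with WT to ask how tau mice that had also lost 1 copy of Lsd1 differed from wild type, so the transgene and the Lsd1 dose differed together. Itgax stood at 18.4 ± 9.3 CPM, Cst7 at 8.18 ± 2.91, Clec7a at 11.4 ± 4.98 and Gfap at 1940 ± 459 (SD, n = 4 each), against the WT levels given above, and DESeq2 called all of these (adjusted p = 5.17e-11, 4.09e-09, 5.17e-06 and 2.45e-05). C3 stood at 26.8 ± 1.42 CPM and C4b at 312 ± 89.3, Cxcl10 at 4.52 ± 2.32 and Cd74 at 53.4 ± 32.6 (DESeq2 adjusted p = 9.21e-05, 0.00134, 3.32e-07 and 0.000295), and Lcn2, a siderophore-binding protein of reactive astrocytes, at 2.05 ± 1.26 against 0.0903 (adjusted p = 0.0029). Interferon response was higher in 25 of 25 genes at a median of 2.12 (camera, adjusted p = 1.39e-33, adjusted p = 0.052 with an estimated correlation), and edgeR called 23 adjusted over the list alone, 0 over all genes, and DESeq2 13. Disease-associated microglia were higher in 28 of 30 genes at 1.63 (camera, adjusted p = 2.03e-27, 0.052 with an estimated correlation; 22 adjusted over the list alone, 0 over all genes, 12 by DESeq2). Complement and Fc receptors were higher in 16 of 16 at 1.7 (adjusted p = 5.48e-21; 0.052; 14, 0 and 7 genes in the same order). Antigen presentation stood at a median of 1.51 (camera, adjusted p = 1.67e-17, adjusted p = 0.0792 with an estimated correlation; 10, 0 and 6 genes) and reactive astrocytes at 1.73 (adjusted p = 1.06e-24; 0.052; 18, 0 and 7). Within replicates 1 and 2 the camera adjusted p of these 5 lists ran from 2.09e-14 (interferon response) to 1.79e-07 (antigen presentation). Within 3 and 4 it ran from 8.27e-22 to 9.09e-12 (same lists). By fry the same 5 lists passed (adjusted p = 0.0113, and 0.0316 for antigen presentation), as did oligodendrocytes and myelin (median 0.38, camera adjusted p = 2.16e-05, 0.0807 with an estimated correlation; fry 0.0392; 9.11e-12 within replicates 1 and 2, 0.0808 within 3 and 4).

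Several neuronal lists, though not CA3 markers (adjusted p = 0.243), were lower in PS19_Lsd1het than in WT by camera. Synaptic genes were lower in 30 of 32 at a median of -0.41 (adjusted p = 9.15e-06, adjusted p = 0.14 with an estimated correlation). Their mean level was 8.14 log2 CPM in PS19_Lsd1het replicate 2 against 8.97, 8.8 and 8.86 in replicates 1, 3 and 4 and 9.01 to 9.14 in WT, and the list was called without that library (adjusted p = 0.00191). GABAergic markers (-0.39, adjusted p = 0.0308, 0.137 with an estimated correlation) were lost without WT replicate 2 (0.0798) or 3 (0.206) or PS19_Lsd1het replicate 3 (0.0538) or 4 (0.115), and within replicates 1 and 2 (0.45). Dentate granule markers stood at -0.46 (adjusted p = 0.00116, 0.179 with an estimated correlation; 0.0992 within replicates 1 and 2, 0.000438 within 3 and 4). CA1 markers stood at -0.33 (adjusted p = 0.00135, 0.369 with an estimated correlation) and were not called without PS19_Lsd1het replicate 2 (adjusted p = 0.379), a library whose cerebellar markers lay a median of 6.27 on the log2 scale above the other 3 libraries of its group, or within replicates 3 and 4 alone (0.952). Immediate early genes, markers of recent neuronal activity, stood at -0.54 (adjusted p = 0.019, 0.55 with an estimated correlation) and were not called with the replicate block (0.0761), without WT replicate 1 (0.225) or 2 (0.472), or without PS19_Lsd1het replicate 2 (0.21) or 4 (0.189). Within replicates 1 and 2 they gave adjusted p = 6.23e-06, and within 3 and 4 the direction turned (0.706). Choroid plexus had a median of 0.66 while the test pointed down (adjusted p = 0.951). In all, 20 lists were called by camera, 0 with an estimated correlation and 6 by fry. The block also ended the calls of cholesterol synthesis (0.057), striatum (0.0557) and neocortex (0.057). Cholesterol synthesis was also lost without WT replicate 1 (0.224) or 2 (0.222) or PS19_Lsd1het replicate 4 (0.139). Striatum was lost without WT replicate 3 (0.121) or 4 (0.388) or PS19_Lsd1het replicate 1 (0.128) or 4 (0.189). Neocortex was lost without WT replicate 1 (0.0832), 2 (0.0649), 3 (0.0926) or 4 (0.117) or PS19_Lsd1het replicate 1 (0.102), 2 (0.341) or 4 (0.13). The edgeR test called 1 gene, Lamr1-ps1 (at least 79.4-fold, adjusted p = 0.0021), with 1270 at an unadjusted p under 0.05 against 1006 by chance. DESeq2 called 106 higher and 4 lower, the latter including mt-Co3 (2.56 ± 0.809 CPM) and Frem3, an extracellular matrix gene (1.09 ± 0.588 against 2.87 ± 0.328; adjusted p = 0.0436). With the block edgeR called 4, among them Itgax (adjusted p = 0.0208), and DESeq2 872. Fitted on these 2 groups alone, edgeR called 22.

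Comparing PS19_Lsd1het with PS19 asked what losing 1 copy of Lsd1 did among tau mice. No glial or immune list passed the test. Interferon response stood at a median of -0.53 (camera, adjusted p = 0.058) and antigen presentation at -0.4 (adjusted p = 0.977). Disease-associated microglia, complement and reactive astrocytes had medians of -0.14, -0.18 and -0.08 while their tests pointed up (adjusted p = 0.47, 0.449 and 0.421). Camera called 9 lists, 0 with an estimated correlation and 0 by fry. Heat shock genes, which encode protein chaperones, were lower in 12 of 12 at -0.5 (adjusted p = 1.74e-05, adjusted p = 0.388 with an estimated correlation; 0.0203 within replicates 1 and 2, 5.08e-05 within 3 and 4). Oxidative phosphorylation was higher in 57 of 71 at 0.12 (adjusted p = 0.000878, 0.388 with an estimated correlation). Immediate early genes stood at -0.66 (adjusted p = 8.68e-06, 0.421 with an estimated correlation; 9.01e-08 and 0.495 within the sets; 0.0658 without PS19 replicate 2). Without PS19_Lsd1het replicate 2 the calls of CA1 markers (-0.25, adjusted p = 0.000172, 0.388 with an estimated correlation) and synapse (-0.22, adjusted p = 0.00134; 0.388) ended, at 0.89 and 0.389, and synapse was also lost without PS19 replicate 2 (0.217). Within replicates 3 and 4 alone synapse gave 0.46, and CA1 markers turned in direction (0.609). Striatal markers, higher in 10 of 10 at 0.77 (adjusted p = 0.00134, 0.388 with an estimated correlation), were lost without the library labelled PS19_Lsd1het replicate 3 (0.542) and within replicates 1 and 2 (0.765). Dentate granule markers (-0.34, adjusted p = 0.00317, 0.388 with an estimated correlation) were lost without PS19 replicate 3 (0.0719) or PS19_Lsd1het replicate 2 (0.0591) or 3 (0.228), and within replicates 1 and 2 (0.37). Choroid plexus (-0.16, adjusted p = 3.79e-05, 0.568 with an estimated correlation) was lost without PS19_Lsd1het replicate 2 (0.0738) or 3 (0.446), and within replicates 3 and 4 (0.0574). Mural cells and fibroblasts (-0.35, adjusted p = 0.0144, 0.505 with an estimated correlation) were lost with the block (0.0541) and without PS19 replicate 1 (0.933) or PS19_Lsd1het replicate 3 (0.615) or 4 (0.0573), and within replicates 1 and 2 (0.327). Camera called 14, 14 and 15 lists without PS19 replicates 1, 2 and 3, and 15 without libraries over 10% mitochondrial counts.

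Few single genes were called between PS19_Lsd1het and PS19. This does not show that differences were small, since low p were fewer than chance gives. By edgeR 0 of 20122 genes were called, with 252 at an unadjusted p under 0.05 against 1006 by chance, and DESeq2 called 1, or 3 with the replicate block. The call was Capn11 (chromosome 17, 45630204 to 45659325), at 3.64 ± 1.3 CPM against 0.363 ± 0.232 (log2 difference 3.26, SE 0.66; adjusted p = 0.00516 by DESeq2 and 1 by edgeR), while the WT libraries read 4.31, 0.706, 2.34 and 0.768. Others of the lowest p stood at 0.793 ± 0.251 against 0.354 ± 0.0532 CPM for Itgb1bp2 and 4.8 ± 6.18 against 0.848 for the metalloprotease gene Adamts18, both at adjusted p = 1 by edgeR. Adamts18 read 14.1 CPM in PS19_Lsd1het replicate 2 and 1.62, 1.75 and 1.76 in replicates 1, 3 and 4. Slc6a5, a glycine transporter of brainstem and cord, read 158 CPM in PS19_Lsd1het replicate 2 against a mean of 0.106 in PS19. Skor1 stood at 4.58 ± 8.6 against 0.145, with 17.5 in PS19_Lsd1het replicate 2.

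Lsd1het against WT, and the interaction of tau with Lsd1 dose, asked what the lost copy did without the transgene and whether its effect differed in tau mice. Without tau, immediate early genes were higher in 16 of 16 at a median of 0.75 (camera, adjusted p = 0.000411, adjusted p = 0.98 with an estimated correlation; 0.153 within replicates 1 and 2). Lsd1het held only replicates 1 and 2, where WT also held 3 and 4. Over WT, mean log2 levels in 3 and 4 differed from those in 1 and 2 by -1.43 for this list. For the unfolded protein and integrated stress response they differed by -0.53, and for striatal markers by 1.37. Each leans toward the change called, so Lsd1 dose and replicate set cannot be told apart over all libraries. Within replicates 1 and 2 the unfolded protein list passed (camera, adjusted p = 0.0189). The unfolded protein and integrated stress response was higher in 20 of 21 at 0.38 (adjusted p = 0.00408, 0.98 with an estimated correlation; 0.498 without Lsd1het replicate 2). Striatal markers stood at -1.52 (adjusted p = 0.0092, 0.98 with an estimated correlation; 0.155 without WT replicate 4, 0.0942 without Lsd1het replicate 2, 0.324 within replicates 1 and 2). Interferon response stood at -0.26 (adjusted p = 0.686) and the disease-associated microglia list gave adjusted p = 0.96. Camera called these 3 lists, and 6 without WT replicate 3, 8 without Lsd1het replicate 1 and 6 without libraries over 10% mitochondrial counts. By edgeR 0 genes were called, with 257 at an unadjusted p under 0.05 against 1006 by chance. DESeq2 called 1, Mir6236, with 3 reads over the Lsd1het libraries against 4230 over WT (adjusted p = 0.0258). It read 20.9, 4.61, 17.9 and 141 CPM over WT replicates 1 to 4, and 0.127 and 0 over Lsd1het. Its count is uncertain because near-identical copies may share its reads. Only the Lsd1het files name a raw read file in their headers. Processing and genotype thus cannot be told apart for this gene, nor for any other gene or list of this comparison or the interaction. Genes of lowest p were Mcmdc2, a meiotic gene, at 1.82 ± 0.654 CPM against 0.118, the serotonin receptor Htr1d at 0.0754 against 0.722, Capn11 at 0.338 against 2.03, and Tgtp2, an interferon-induced GTPase, at least 4.1-fold lower, all with edgeR adjusted p above the threshold.

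In the interaction, immediate early genes stood at -1.13 with 0 of 16 positive (camera, adjusted p = 9.08e-12, adjusted p = 0.578 with an estimated correlation; 4.14e-08 within replicates 1 and 2). Over all libraries their direction against the matching control was opposite with and without tau. The rise without tau did not pass within replicates 1 and 2 (camera, adjusted p = 0.153), the only ones of Lsd1het, so opposite directions are not established. Striatal markers stood at 2.21 with 10 of 10 positive (adjusted p = 9.77e-07, 0.578 with an estimated correlation; 0.365 within replicates 1 and 2). The unfolded protein and integrated stress response stood at -0.46 (adjusted p = 0.00117, 0.724 with an estimated correlation; 0.187 without Lsd1het replicate 2) and CA1 markers at -0.49 (adjusted p = 0.0115, 0.724 with an estimated correlation; 0.0713 without PS19 replicate 3, 0.68 without PS19_Lsd1het replicate 2). Interferon response gave adjusted p = 0.902 and disease-associated microglia 0.854, so no difference in those lists was detectable. Camera called these 4 lists, and 10 without WT replicate 3, 9, 11 and 7 without PS19 replicates 1, 2 and 4, and 8 without PS19_Lsd1het replicate 1 or 4 or Lsd1het replicate 1. By edgeR 0 genes were called, with 168 at an unadjusted p under 0.05 against 1006 by chance. DESeq2 called 2, Capn11 (log2 difference 5.83, SE 1.11; adjusted p = 0.000236) and the pseudogene Gm13453 (-8.18; adjusted p = 0.00824), whose count is uncertain.

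At 11 months, PS19_HA was compared with WT_HA to ask what the tau transgene changed in mice given the control virus. Disease-associated microglia were higher in 28 of 29 genes at a median of 1.34 (camera, adjusted p = 2.29e-16, adjusted p = 0.246 with an estimated correlation), with 21 called by edgeR adjusted over the list alone, 0 over all genes and 12 by DESeq2. Cst7 stood at 5.2 ± 6.15 CPM against 0.151 and Clec7a at 14.6 ± 16.7 against 0.565 (SD, n = 3 each; DESeq2 adjusted p = 0.00015 and 0.0052). Interferon response was higher in 25 of 25 at 1.13 (adjusted p = 1.03e-17, 0.246 with an estimated correlation), with 18 called adjusted over the list alone, 0 over all genes and 5 by DESeq2. Among them, Lgals3bp, a secreted galectin-binding glycoprotein, stood at 37.9 ± 14.7 against 11.9 ± 1.1 and Bst2, an antiviral tether, at 6.88 ± 1.32 against 2.23 ± 0.75 (DESeq2 adjusted p = 1.79e-05 and 0.000754). Antigen presentation was higher in 17 of 17 at 1.26 (adjusted p = 7.92e-14, 0.246 with an estimated correlation; 13, 0 and 5 genes in the same order). Complement and Fc receptors were higher in 15 of 16 at 1.34 (adjusted p = 3.26e-09, 0.302 with an estimated correlation; 11, 0 and 6), with C4b at 254 ± 124 against 52.6 ± 15.4 CPM (DESeq2 adjusted p = 2.09e-06). Reactive astrocytes were higher in 21 of 24 at 1.22 (adjusted p = 1.82e-11, 0.246 with an estimated correlation; 12, 0 and 4), with Gfap at 948 ± 476 against 271 ± 43 (DESeq2 adjusted p = 0.000483). Ctsc, a lysosomal protease that activates other proteases, stood at 23.9 ± 3.5 against 11.3 ± 0.97 (DESeq2 adjusted p = 0.00024). Mean levels of these 5 lists separated both PS19_HA and PS19_LSD1 completely from WT_HA, with p = 0.1 by exact permutation, the smallest 3 libraries against 3 allow (adjusted p = 0.344).

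Choroid plexus markers were higher in PS19_HA in 14 of 14 at a median of 2.26 (camera, adjusted p = 8.63e-07, adjusted p = 0.416 with an estimated correlation), but their mean level ranged from 0.37 to 4.4 log2 CPM over the WT_HA libraries and from 2.99 to 6.18 over PS19_HA. Oligodendrocyte and myelin genes were higher in 17 of 17 at 0.63 (adjusted p = 1.1e-07, 0.416 with an estimated correlation), homeostatic microglia stood at 0.49 (adjusted p = 2.51e-05; 0.246), and synapse at -0.15 (adjusted p = 0.00236; 0.533; 0.073 without WT_HA replicate 2). T-cell genes stood at 1.04 (adjusted p = 0.00363, 0.246 with an estimated correlation; 0.0585 without PS19_HA replicate 3). Striatal markers (-0.57, adjusted p = 0.0602) passed with the replicate block (3.39e-05), though not with the block and an estimated correlation. Camera called 16 lists, and 0 with an estimated correlation or by fry. Genes lower by DESeq2 included Tshz2, a zinc finger gene of cortical and subicular neurons, at 9.66 ± 4.02 against 23 ± 2.32 CPM (adjusted p = 0.00478), and Snhg14, a long non-coding RNA of neurons, at 95 ± 9.76 against 140 ± 6.58 (adjusted p = 0.000335).

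Over all 19290 genes, edgeR called 2 higher and 1 lower in PS19_HA, with 1665 at an unadjusted p under 0.05 against 964 by chance, and DESeq2 105 higher and 16 lower. The 3 were Lamr1-ps1 (at least 60.2-fold, adjusted p = 0.0255), the non-coding RNA 4930590L14Rik (chromosome 3, 140951876 to 140953247; 1.74 ± 0.211 against 0.0541 CPM, adjusted p = 0.0455) and mt-Nd4l (0.695 ± 0.189 against 6.67 ± 1.91, adjusted p = 0.0255), which has nuclear copies and so an uncertain level. 4930590L14Rik was chosen after its values were seen and was not called with the block (adjusted p = 0.0655), where its fitted log2 difference was 5.05 as without it, a value that rests on reads of 0, 2 and 1 in the WT_HA libraries. Gbp2b, an interferon-induced GTPase (chromosome 3, 142594847 to 142619179), had 0 reads in WT_HA and was at least 92.8-fold higher, which passed by DESeq2 (adjusted p = 1.33e-08) and not by edgeR (0.0799). With sex as a covariate edgeR called 0 genes, and with the block DESeq2 called 266. The edgeR test called 1 gene without WT_HA replicate 1, 0 without WT_HA replicate 2 or 3 or PS19_HA replicate 2 or 3, and 8 without PS19_HA replicate 1.

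PS19_LSD1 was compared with PS19_HA to ask what added LSD1 changed in tau mice. Disease-associated microglia were lower in 27 of 29 genes at a median of -0.65 (camera, adjusted p = 5.21e-07, adjusted p = 0.847 with an estimated correlation). Complement and Fc receptors stood at -0.52 (adjusted p = 0.00409, 0.895 with an estimated correlation) and reactive astrocytes were lower in 20 of 24 at -0.42 (adjusted p = 0.000118, 0.847 with an estimated correlation). All 3 calls ended without PS19_HA replicate 3, at 0.538, 0.82 with the direction turned, and 0.533. Levels of regional markers spread within PS19_HA, from 4.9 to 6.18 log2 CPM for CA1, 4.15 to 5.59 for dentate granule neurons and 3.2 to 5.05 for thalamus. Thalamus markers also ran from 3.19 to 5.27 in WT_HA and 3.12 to 5.66 in PS19_LSD1. Uneven regional content was not tested as a source of these calls. Mean levels of disease-associated microglia were 4.77 ± 0.89 log2 CPM in PS19_HA and 4.25 ± 0.31 in PS19_LSD1 (SD, n = 3 each), against 3.41 ± 0.09 in WT_HA. Interferon response stood at 0.1 (adjusted p = 0.368) and antigen presentation at -0.27 (adjusted p = 0.216). Choroid plexus was lower in 14 of 14 at -1.35 (adjusted p = 5.21e-07, 0.847 with an estimated correlation), but its mean level was 5.74, 6.18 and 2.99 log2 CPM over the PS19_HA libraries and 1.34, 2.2 and 5.5 over PS19_LSD1, so the groups overlapped. Oxidative phosphorylation was higher in 66 of 71 at 0.06 (adjusted p = 9.49e-05; 0.847; 0.119 without PS19_HA replicate 2). Heat shock stood at 0.11 (adjusted p = 0.00908, 0.847 with an estimated correlation), and was lost without PS19_HA replicate 1 (0.0533) or 3 (0.0695). CA1 markers stood at 0.27 (adjusted p = 0.0347; 0.847), and were lost without PS19_HA replicate 3 (0.713) or PS19_LSD1 replicate 1 (0.447) or 2 (0.123). Homeostatic microglia (-0.26, adjusted p = 0.0147; 0.847) were lost without PS19_HA replicate 2 (0.138) or 3 (0.538). Immediate early genes (-0.21, adjusted p = 0.0475; 0.847) were lost with the block (0.149), and without PS19_HA replicate 1 (0.0927) or 3 (0.629) or PS19_LSD1 replicate 3 (0.932, direction turned). Camera called 9 lists, 0 with an estimated correlation or by fry, and 14 and 16 without PS19_LSD1 replicates 2 and 3. Each of the 10 ways to regroup these libraries, the real one included, called at least 9 lists.

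Few single genes other than Kdm1a were called between PS19_LSD1 and PS19_HA. This does not show that differences were small, since low p were fewer than chance gives. By edgeR 0 genes were called, with 350 at an unadjusted p under 0.05 against 964 by chance, and 1 without PS19_LSD1 replicate 1 or 3. With the replicate block DESeq2 called 7 higher and 9 lower, and fewer without it. DESeq2 called 1 higher, Kdm1a, and 2 lower, Gm5148, annotated as protein-coding (0.114 ± 0.0569 against 3.12 ± 0.378 CPM; adjusted p = 0.00418), named after its values were seen, and the immunoglobulin gene Ighg1 (0.118 ± 0.119 against 2.82 ± 2.17; adjusted p = 0.0279). Levels of Gm5148 also spread within groups without added LSD1, at 0.169, 4.23 and 3.4 CPM over WT_HA, 2.97, 0.0831, 6.03 and 6.38 over WT and 0, 1.77, 5.44 and 3.43 over PS19. Tshz2, lower in PS19_HA than in WT_HA, stood at 21.3 ± 3.45 CPM in PS19_LSD1 (adjusted p = 1 by edgeR), and was called adjusted over the neocortex list alone. Clec9a, a receptor of dendritic cells, stood at 1.14 ± 0.124 against 0.263 and the protocadherin Pcdhga2 at 8.53 against 13.

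Against WT_HA, PS19_LSD1 libraries showed what remained in tau mice with added LSD1. Interferon response was higher in 25 of 25 genes at a median of 1.24 (camera, adjusted p = 2.57e-26, adjusted p = 0.269 with an estimated correlation), with 20 called by edgeR adjusted over the list alone, 0 over all genes and 1 by DESeq2, Cxcl10 at 2.98 ± 1.62 CPM (adjusted p = 0.0231). Antigen presentation was higher in 17 of 17 at 0.95 (adjusted p = 6.46e-14, 0.269 with an estimated correlation; 10 adjusted over the list alone, 0 over all genes by edgeR or DESeq2). Disease-associated microglia stood at 0.69 (adjusted p = 1.56e-09, 0.468 with an estimated correlation), complement at 0.7 (adjusted p = 2.88e-06; 0.468) and reactive astrocytes at 0.63 (adjusted p = 1.01e-06; 0.468), and edgeR called 0, 1 and 0 of their genes adjusted over the list alone. C4b stood at 175 ± 21.2 CPM and Cst7 at 2.18 ± 1.42 (DESeq2 adjusted p = 0.00482 and 0.0498). Oligodendrocytes and myelin stood at 0.58 (adjusted p = 1.92e-07, 0.468 with an estimated correlation) and synapse at -0.18 (adjusted p = 0.00011; 0.468; 0.374 without PS19_LSD1 replicate 3). With the block, striatum (-0.29, adjusted p = 5.81e-05), cholesterol synthesis (-0.09, 0.0365), red blood cells (0.43, 0.00685) and neocortex (-0.26, 0.00685) passed, which did not without it. None of them passed with the block and an estimated correlation. Camera called 12 lists, and 0 with an estimated correlation or by fry. The edgeR test called 3 genes higher and 1 lower, with 773 at an unadjusted p under 0.05 against 964 by chance, and DESeq2 16 and 2. The 4 were Kdm1a, Lamr1-ps1 (at least 45.2-fold, adjusted p = 0.0312), 4930590L14Rik (1.8 ± 0.331 CPM, adjusted p = 0.0319) and mt-Nd4l (0.806 ± 0.0873, adjusted p = 0.0312). These edgeR calls numbered 0 with the block, where DESeq2 called 42, and 0 with the sex covariate. They numbered 2 without WT_HA replicate 1, 0 without WT_HA replicate 2 or 3 or PS19_LSD1 replicate 2, and 1 without PS19_LSD1 replicate 1.

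The tau effects of the 2 cohorts were then compared, with age, injection, the mix of male-type and female-type libraries and any sequencing batch differing together between them. The interferon list rose less at 11 months, with 0 of 25 genes positive in the difference and a median of -1.52 (camera, adjusted p = 7.43e-30, adjusted p = 0.118 with an estimated correlation), and edgeR called 2 genes lower adjusted over the list alone and 0 over all genes. Antigen presentation (-0.8, adjusted p = 3.37e-05, 0.466 with an estimated correlation), complement (-0.63, adjusted p = 3.8e-06; 0.427) and reactive astrocytes (-0.62, adjusted p = 3.83e-06; 0.427) were also lower in the difference. Choroid plexus was higher at 1.3 (adjusted p = 0.000502, 0.681 with an estimated correlation). Genes of lowest p were the interferon-induced Ifit1 (-2.35, SE 0.7), Zbp1 (-3.59) and Oasl1 (-3.7), all at adjusted p = 1 by edgeR. Both edgeR and DESeq2 called 0 genes, with 119 at an unadjusted p under 0.05 by edgeR against 1047 by chance.

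Genes called in both cohorts were counted in fits that share no library. The edgeR test called 1 gene in both, Lamr1-ps1, against 0.000105 for independent lists. Lamr1-ps1 had reads in each library with the transgene and none in the libraries without it. Its sharing thus tracks the transgene and does not measure a shared response to tau. Of the 187 higher genes of DESeq2 at 9 months and the 105 at 11 months, 50 were shared among 18981 genes tested in both, against 1.03 for independent lists, and of the 4 and 16 lower genes 0 were shared, against 0.00337. Only 177 of the 187 and 98 of the 105 were tested in both cohorts, so 1.03 is slightly too high. The genes DESeq2 called higher in PS19 at 9 months were lower in PS19_LSD1 than in PS19_HA in 145 of 177, at a median of -0.42 (camera p = 3.32e-09; p = 0.333 with an estimated correlation; fry p = 0.46). This set, and the 121 genes below, were tested on all libraries only. In the same comparison the camera calls of disease-associated microglia, complement and reactive astrocytes ended without PS19_HA replicate 3. The edgeR set, Lamr1-ps1 alone, stood at -0.41 and did not pass, and as it tracks the transgene it does not bear on a rescue. The 98 genes DESeq2 called higher in PS19_HA stood at -0.14 between PS19_Lsd1het and PS19 (camera p = 0.19), and the 16 called lower at -0.33 (camera p = 7.39e-05; p = 0.219 with an estimated correlation). Of the 121 genes DESeq2 called between PS19_HA and WT_HA, 117 (96.7%) moved the opposite way between PS19_LSD1 and PS19_HA, a share that shared PS19_HA libraries raise without any effect. In 15 simulations of unchanged rescue libraries it was 72.8%, from 70.6% to 74.5%, and the median change of the higher genes was -0.18 there, from -0.2 to -0.14, against -0.65 observed. The simulated sets held 918 to 1069 DESeq2 calls each against the 121 observed, and the simulation left out the replicate pairing, so the shares come from unlike sets of calls and their gap is not a test. For the 3 genes of edgeR it was 2, or 66.7%, against a simulated 74% over sets of 305 to 414 calls.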

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

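All tests of other splits of the samples, and the test of Lamr1-ps1 in PS19_Lsd1het replicate 2, were chosen after the results were seen. The tests of mitochondrial share, GC content, gene length, cerebellar and brainstem markers and the chromosome 3 window were written before theirs were seen.

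Replicates 3 and 4 of the 9-month groups lay apart from replicates 1 and 2, with 7645 genes higher and 7070 lower in replicates 3 and 4 in all 3 of WT, PS19 and PS19_Lsd1het, of 20122. High mitochondrial shares as the whole cause are argued against, since the gap on the first principal component was 0.34 of its range with all 14 libraries and 0.74 in the 12 without those over 10%. A gene length bias is argued against by rank correlations across genes of 0.12, 0.11 and 0.07. GC content stays open as a candidate explanation, with rank correlations of -0.75, -0.76 and -0.62 over 99.9% of the genes, which are not independent replicates. No biological explanation was tested, because the labels say nothing of what the numbers share.

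PS19_Lsd1het replicate 2 carried genes that the other 13 libraries of its cohort had at lower levels. Its 10 cerebellar markers lay at a median of 6.27 on the log2 scale above the other 3 libraries of its group, where no other library passed 1.48, with Fat2 at 523 CPM against at most 24.7, Cbln1 at 504 against at most 28.2, Zic1 at 598 against at most 92.8 and Zic2 at 156 against at most 45.6. Its 8 markers of brainstem and cord lay at a median of 6, with Glra1 at 30.9 CPM against at most 0.363 and Hoxb5 at 19.5 against 0. RNA of both regions may thus be in this library, as a hypothesis. A library of a mouse without the transgene is argued against by Lamr1-ps1, at 2.28 CPM there.

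Genes around 140 Mb of chromosome 3 were higher in tau libraries of both cohorts: 4930590L14Rik was at least 37.2-fold higher at 9 months and stood at 1.74 against 0.0541 CPM at 11 months, and Gbp2b was higher by 4.48 on the log2 scale and at least 92.8-fold. Of 64 other genes from 5 Mb below to 6 Mb above that point, 4 (6.25%) had an unadjusted p under 0.05 in both cohorts, against 403 of 18915 (2.13%) elsewhere (permutation p = 0.0478 over 10000 draws; 0.0753 for runs of neighbours). That p met what a segment of another strain beside the transgene would give, yet 3 of the 4, Gbp2, Gbp3 and Gbp7, are interferon-induced and the interferon list rose, so the reading was lowered after the result was seen. Without Gbp genes, a choice made after, 1 of 60 passed (permutation p = 0.729). A strain segment and a few genes at the insertion site alone cannot be told apart, since the remaining genes are too few.

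Chance was tested by regrouping the samples, taking the libraries as exchangeable. By the correlation rule, the numbers were taken to pair the 9-month libraries of these comparisons. Between PS19_Lsd1het and PS19, 0 of 4 libraries correlated best with their own number, so the pairing is uncertain there. The 8 splits that part every pair are too few for a share under 0.05, so chance is not taken as excluded for any of these counts. Over all 35 splits, for PS19 against WT, the share as large was under 0.05 for interferon genes called over the list alone (25; 1 split as large, highest other 22), but not for DESeq2 genes (191; 5 splits, highest other 9522), edgeR genes (1; 3 splits, 8611) or lists (18; 2 splits, 18). For PS19_Lsd1het against WT it was under 0.05 for lists (20; 1 split, highest other 17) and interferon genes (23; 1 split, highest other 0), but not for DESeq2 genes (110; 3 splits, 5928) or edgeR genes (1; 2 splits, 1). For PS19_Lsd1het against PS19 it was not under 0.05 for DESeq2 genes (1; 20 splits, 4440), edgeR genes (0; 35 splits, 0), lists (9; 25 splits, 19) or interferon genes (0; 35 splits, 15). In all 3 comparisons the split with the highest DESeq2 count set replicates 1 and 2 against 3 and 4, which points to a structure of the samples. With the replicate block DESeq2 called 365, 872 and 3 genes, and within either set edgeR called 0 between either tau group and WT. Beside the real one, the splits that part every pair mix genotypes on each side. They gave at most 98, 39 and 3 DESeq2 genes, 18, 17 and 19 lists and 22, 0 and 0 interferon genes in the same order.

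At 11 months the 10 splits are too few for a share under 0.05. For PS19_HA against WT_HA the real count and the highest other were 121 and 152 for DESeq2 genes, 3 and 0 for edgeR genes, 16 and 20 for lists and 18 and 2 for interferon genes. For PS19_LSD1 against PS19_HA they were 3 and 137, 0 and 1, 9 and 17, and 0 and 6 in the same order, and for PS19_LSD1 against WT_HA 18 and 273, 4 and 0, 12 and 12, and 20 and 0. In both latter comparisons another split called many times the real DESeq2 count, which points to a structure of the samples. These set PS19_HA replicates 1 and 2 with PS19_LSD1 replicate 3, and WT_HA replicate 1 with PS19_LSD1 replicates 1 and 2. The former split parts the libraries with high choroid plexus levels from those with low levels, as given in the results. Whether choroid plexus RNA sets that count was not tested. Between PS19_LSD1 and PS19_HA, all 10 splits called at least the 9 lists of the real one. With the block DESeq2 called 42 genes between PS19_LSD1 and WT_HA. For the difference of the tau effects, 15 splits are also too few, with 0 edgeR genes and at most 1811 in another.

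In 12 of 210 groups of 4 libraries, 1 lay far from the others, where chance gives about 1 in 20. Mitochondrial share was 33.9% in WT replicate 3 and 16.1% in PS19 replicate 3. C4b was at 3.35 log2 CPM in WT replicate 3, and Ccl5 at -2.19 in WT replicate 4. Mean list levels were 4.08 for mural cells and fibroblasts in PS19 replicate 1, 2.69 for thalamus in PS19 replicate 2, -1.41 for T cells and 4.08 for CA1 in PS19_Lsd1het replicate 2, and 4.56 for striatum in the library labelled PS19_Lsd1het replicate 3. Itgax was at 5.02 in PS19_Lsd1het replicate 4, and Adamts18 at 3.82 and Skor1 at 4.14 in PS19_Lsd1het replicate 2.

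Lists differed between groups in the interaction of tau and Lsd1 dose for CA1 (camera, adjusted p = 0.0115), immediate early genes (9.08e-12), the unfolded protein and integrated stress response (0.00117) and striatum (9.77e-07), none of them with an estimated correlation. Tau effects differed between cohorts by camera for disease-associated microglia (adjusted p = 0.00239), complement (3.8e-06), interferon response (7.43e-30), antigen presentation (3.37e-05), T cells (0.00231), reactive astrocytes (3.83e-06), astrocyte core (0.0104), oligodendrocytes (0.0467), p53 targets (0.0409), heat shock (0.00284), endothelium (0.00276), mural cells (0.00231) and choroid plexus (0.000502), again none with an estimated correlation. Outside the comparisons, Y-linked genes summed to 20.6 CPM in WT_HA replicate 2 and 18.6 in PS19_HA replicate 2, both with high Xist, and Xist read 42.5 CPM in WT_HA replicate 3 and 64 in PS19_LSD1 replicate 1, both with high Y-linked counts.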

How the results depend on the processing

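Chosen after seeing the data were fits with the 2-level covariate, of replicates 1 and 2 or 3 and 4 alone, without libraries over 10% mitochondrial counts, and with robust estimation off. So were DESeq2 with the block, with the covariate, without single libraries or those over 10%, and DESeq2 for shared calls and as the source of gene sets. List tests with the sex covariate, or with an estimated correlation beside the block, the covariate or the left-out libraries, were also chosen then. For named genes, 2370 values kept their direction and side of the threshold over the alternatives, 513 passed where the first fit did not and 70 were lost. For lists 1061 kept both, 591 were lost and 7 turned. The cause of changes was not tested except where fewer samples or another tool define the alternative. Depth, at 15451494 to 24644977 counted reads, limits genes of a few counts most.

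For genes called, PS19 against WT at 9 months, edgeR gave 9 with no filter, 5 with the replicate block, 0 with the compared groups alone, 92 with all 23 libraries, 9 with the 2-level covariate, and 0 in replicates 1 and 2 or 3 and 4 alone. DESeq2 gave 191, 365 with the block, 297 with the covariate and 256 without libraries over 10% mitochondrial counts. Leaving out 1 library gave 1 to 146, the latter without PS19 replicate 2, and 2 without PS19 replicate 3. For genes called, PS19_Lsd1het against WT at 9 months, edgeR gave 2, 4, 22 and 12 for no filter, block, compared groups and all libraries, and 0 in either set. DESeq2 gave 110, 872 with the block, 413 with the covariate, 114 without libraries over 10% mitochondrial counts, and 83 and 74 without PS19_Lsd1het replicates 2 and 3. For genes called, PS19_Lsd1het against PS19 at 9 months, DESeq2 gave 1, 3, 2, 2, 1 and 3 in the same order, where edgeR gave 0. For Lsd1het against WT DESeq2 gave 1, 2 with the block, 1 with the covariate and 1 without libraries over 10% mitochondrial counts, and for the interaction 2, 4, 3 and 1, and 2 without PS19_Lsd1het replicate 2 or 3.

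For genes called, PS19_HA against WT_HA at 11 months, edgeR gave 5 with no filter, 0 with the sex covariate, 0 with the compared groups alone, 1 with all libraries and 0 without libraries over 10% mitochondrial counts. DESeq2 gave 121, 266 with the block and 60 without those libraries. Leaving out 1 library gave 0 (WT_HA replicate 2 or 3, PS19_HA replicate 2 or 3) to 8 (PS19_HA replicate 1), with 1 without WT_HA replicate 1. For genes called, PS19_LSD1 against PS19_HA at 11 months, edgeR gave 1 with all libraries and 0 to 1 leaving out 1 library (1 without PS19_LSD1 replicate 1 or 3). DESeq2 gave 3, 16 with the block and 2 without libraries over 10% mitochondrial counts. For genes called, PS19_LSD1 against WT_HA at 11 months, edgeR gave 0 with the block, the sex covariate, the compared groups alone and without libraries over 10% mitochondrial counts, and 0 (WT_HA replicate 2 or 3, PS19_LSD1 replicate 2) to 3 (PS19_LSD1 replicate 3) leaving out 1, with 2 without WT_HA replicate 1 and 1 without PS19_LSD1 replicate 1. DESeq2 gave 18, 42 with the block and 12 without libraries over 10% mitochondrial counts. For the difference of tau effects DESeq2 with the block gave 2.

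Lists called with an estimated correlation numbered 6 for PS19 against WT and 0 in each of the other 8 comparisons, and by fry 6 for PS19 against WT, 6 for PS19_Lsd1het against WT and 0 in the other 7. With the block and an estimated correlation they numbered 0 in all 9, with the 2-level covariate and an estimated correlation 0 in all 5 comparisons at 9 months, and without libraries over 10% mitochondrial counts and with an estimated correlation 7 for PS19 against WT and 0 in the other 8. At the preset correlation, Lsd1het against WT gave 7 lists with the block, 8 with the 2-level covariate and 6 without libraries over 10% mitochondrial counts, and 2 (WT replicate 4) to 8 (Lsd1het replicate 1) leaving out 1 library, with 6 without WT replicate 3. Leaving out an Lsd1het library leaves 1, which is assumed to vary like the other groups. The interaction gave 8 with the block, 7 in replicates 1 and 2 alone and 4 (WT replicate 1) to 11 (PS19 replicate 2), with 10 without WT replicate 3, 9 and 7 without PS19 replicates 1 and 4, and 8 without PS19_Lsd1het replicate 1 or 4 or Lsd1het replicate 1. PS19_Lsd1het against WT gave 13 in replicates 3 and 4 alone. PS19_Lsd1het against PS19 gave 15 without libraries over 10% mitochondrial counts and 6 (PS19_Lsd1het replicate 3) to 15 (PS19 replicate 3), with 14 without PS19 replicate 1 or 2. PS19_LSD1 against PS19_HA gave 7 (PS19_HA replicate 3) to 16 (PS19_LSD1 replicate 3), with 14 without PS19_LSD1 replicate 2.

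Directions turned for 7 list values. In replicates 3 and 4 alone these were list immediate early genes, PS19_Lsd1het against WT at 9 months (adjusted p = 0.706 by camera), list cholesterol synthesis, PS19_Lsd1het against WT at 9 months (0.952), and list CA1 pyramidal neurons, PS19_Lsd1het against PS19 at 9 months (0.609). For list oligodendrocytes and myelin, tau effect at 11 months against tau effect at 9 months, they turned without libraries over 10% mitochondrial counts (0.117; adjusted p = 0.71 with an estimated correlation). For list complement and Fc receptors, PS19_LSD1 against PS19_HA at 11 months, leaving out 1 library gave 3.6e-14 (PS19_HA replicate 1) to 0.82 (PS19_HA replicate 3, turned), and for list immediate early genes, PS19_LSD1 against PS19_HA at 11 months, 0.000998 (PS19_LSD1 replicate 1) to 0.932 (PS19_LSD1 replicate 3, turned).

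For shared tau calls of both cohorts, edgeR gave 2 with no filter, 0 with the sex covariate, DESeq2 50, and leaving out 1 library 0 (WT_HA replicates 1 to 3, PS19_HA replicate 2 or 3) to 2 (PS19 replicate 2). For rescue of independent tau genes the DESeq2 set gave -0.42. The edgeR set gave -0.41, and leaving out 1 library -0.91 (PS19 replicate 3) to -0.22 (PS19_LSD1 replicate 3), passing without PS19 replicate 2 (-0.49, where the set held 139 genes) or PS19_LSD1 replicate 2 (-0.71). For Lsd1 dose on independent tau genes the edgeR set gave -0.31, and leaving out 1 library -0.51 (PS19_Lsd1het replicate 4) to -0.12 (PS19_Lsd1het replicate 2), passing without PS19 replicate 1 (-0.46). With the replicate block, lists also passed that did not before: oligodendrocytes (0.0444), synapse (0.0254), dentate granule neurons (7.37e-05) and heat shock (1.48e-05) in the interaction, and red blood cells (0.0324) and striatum (0.0258) in the difference of tau effects. None of these lists passed with the block and an estimated correlation. Beyond these and the values given with the results, the block at the preset correlation changed no other call of a list or named gene by edgeR where the numbers were taken to pair. They did not pair Lsd1het with WT (2 pairs, correlations 0.03 to 0.07, with 2 Lsd1het libraries correlating best with their own number) or PS19_LSD1 with PS19_HA (3 pairs, 0.07 to 0.24, with 2 PS19_LSD1 libraries doing so), where the block moved the list count to 7 from 3 in the former and to 10 from 9 in the latter.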

Other observations

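The immunoglobulin genes were examined after their values were seen. In PS19_HA, 47 of 53 immunoglobulin genes were higher than in WT_HA, at a median of 1.96, and DESeq2 called 6 (camera p = 9.12e-12; p = 0.133 with an estimated correlation; fry p = 0.114). Among them, Ighg1, a heavy chain constant region gene, stood at 2.82 ± 2.17 CPM against 0.129 ± 0.0757 (SD, n = 3 each; adjusted p = 0.00512 by DESeq2 and 0.454 by edgeR). In PS19_LSD1, 17 of the 53 were higher than in PS19_HA, at a median of -0.63 (camera p = 2.6e-05; p = 0.325 with an estimated correlation), and 37 higher than in WT_HA, at 1.38 (camera p = 1.45e-05; p = 0.312 with an estimated correlation). Their summed level per library was 135, 195 and 26.2 CPM in WT_HA, 134, 612 and 403 in PS19_HA and 36.8, 315 and 296 in PS19_LSD1, so the groups overlapped. At 9 months 5 such genes passed the filter and DESeq2 called 0 of them between groups there.

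The mitochondrial genes mt-Nd4l and mt-Co3 varied widely between the WT libraries, and were chosen after their values were seen. Levels of mt-Nd4l were 0.324, 0.415, 129 and 1.05 CPM over the 4 WT libraries, and 4.49, 8.02 and 7.51 over WT_HA. Those of mt-Co3 were 28.8, 121, 11.9 and 4.97 CPM over WT, and 15.2 and 11.2 over Lsd1het. Both have nuclear copies, and how reads with several alignments were counted is not given in the sources used here.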
